A study of Homo sapiens with 4 samples.

How the data were processed

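The series held 4 arrays of total RNA from IMR90 cells, a human fetal lung fibroblast line from ATCC, each carrying 2 RNA samples labelled in different colours. Per the labels, Cy3 marked cells with a control knockdown and Cy5 marked cells with a knockdown of the linker histone H1.5 (2 arrays) or of the deacetylase SIRT1 (2 arrays), all by lentiviral shRNA with 7 days of puromycin selection. RNA was reverse transcribed from random hexamers and labelled with a low-input amplification kit from Agilent. No array had the dyes exchanged, so a dye effect specific to a gene was part of each ratio against control. It cancels in the difference between the knockdowns only if its size was the same on all arrays, which was not tested. The 4 arrays lay on 1 slide that was scanned once, which left no slide or scan to compare.

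The deposited scanner files, written by Agilent Feature Extraction 9.5.3.1 (design 014850), gave each spot's mean signal and local median background as an intensity on a linear scale. The deposited processed signals were also an intensity, after the scanner software had removed spatial trends, replaced values near background and normalized the dyes with a linear factor and a lowess curve. The deposited LogRatio column was the log10 of the processed Cy5 signal over the processed Cy3 signal. Other columns were 0 or 1 marks for spots well above background, saturated spots and outlier spots, per the file headers. The series matrix values were a score that the authors derived from these ratios. Set against the same feature numbers, each of its columns was proportional to the scanner's log10 ratio, with a standard deviation of 1 and a median of 0 on all 4 arrays, so that its scale is in standard deviations of one array. Its direction and centring were those of the scanner's ratio, Cy5 over Cy3, and the reason for the division is not stated. The score was used only as an alternative.

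Values were computed with R 4.3.3 and limma 3.58.1. Background was corrected with normexp (offset 50) on mean signal and median background, and each array was normalized by loess with control spots at weight 0. The offset was added to both channels, which pulls the log2 ratios of dim probes toward 0. The median signal less background was only 2.49 to 8.23 units per array and channel, so changes of dim probes tend to be understated. Spots marked as non-uniform or population outliers in either channel were set missing, saturated spots were kept, and repeated spots of a probe were averaged. Of 45015 spots, 43376 belonged to 41000 gene probes. A probe was kept when it had a value on all 4 arrays and was well above background in the same channel on at least 2 arrays, which left 20153 probes. A gene was represented by its brightest probe, giving 16597 genes, of which 2799 had more than 1 probe. Accessions matched a current symbol for 23434 probes in RefSeq's table for GRCh38.p14, used for names only, and the name in the scanner file was kept otherwise. Unmatched accessions and clone names were counted as genes, so 10471 of the genes tested had a symbol. A gene with probes under both an old and a current symbol was counted more than once. Probe positions are those of the array files, on hg17.

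One limma fit over the 4 arrays gave a coefficient for each knockdown and their difference, so both knockdowns shared 1 estimate of the spread, with 2 residual and 3.14 prior degrees of freedom. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Before the data were examined, 49 gene lists were fixed that fit the cell type and the knockdowns, and the 47 with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01. Each list was tested again with an estimated correlation and with fry, which asks whether the genes of a list move one way on balance without comparing them with other genes. The lists of type I interferons (1 member measured) and sirtuins (3 members) were too small to test.

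The rule for naming genes was fixed at the same time. It took HIST1H1B, which encodes H1.5, and SIRT1, and the 12 largest rises and 12 largest falls of each comparison with control among called genes with a recognised symbol and the same sign on both arrays. It took 6 in each direction for the difference between knockdowns, and up to 4 members with the smallest p of each list described, of which 2 were used for the difference. A few of the genes taken by the rule are not listed in the text. Where the control or knockdown channel of a probe was not well above background, or was saturated, on both arrays of a comparison, the fold is given as a bound. The bound set the mean of the brighter channel against the mean of the dimmer channel, each array's value there being the higher of the probe's own signal and the lowest signal among probes well above background, after loess and Aquantile. Without exchanged dyes these bounds are open to dye bias.

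The alternatives fixed in advance were the scanner's processed signals centred on the median, no background subtraction, median centring in place of loess, Aquantile between arrays, no filter or a strict filter on dim probes, the mean over probes, the series matrix, each knockdown fitted alone, a trended robust prior, the replicate number as a block, each array left out in turn, a size minimum of 1 on the log2 scale, and the other list tests. Alternatives chosen after the data were seen were a normexp offset of 1, a loess curve on probe GC content, probes above 55% GC left out, probes saturated on any array left out, and the H1.5 arrays averaged as 1 replicate.

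The functions were tested on simulated data with the measured spread of the 16597 genes. With 200 genes changed at each size in the H1.5 comparison, 28.0% were called at a log2 change of 0.1, 96.5% at 0.2 and 100% at 0.3, and 4.36% of all calls were false. For the difference between knockdowns, 4.5% were called at 0.1, 76.0% at 0.2 and 98.5% at 0.3, and 5.26% of all calls were false. The labels call the arrays biological replicates. Each array carried 10 spots of some probes, and over 148 of these the difference between the 2 H1.5 arrays was set against the spread of repeated spots. It gave a chi-square per probe of 1.52 (chi-square test across probes, p = 5.31e-05), and 40.0 for the SIRT1 arrays over 146 probes. With outlier spots kept, the values over 148 probes were 1.01 and 6.31. With outlier spots left out the median chi-square was 0.257 for the H1.5 arrays and 0.632 for the SIRT1 arrays, well below the means. On these probes the H1.5 arrays therefore differed by little more than repeated spots on an array. Because the fit shared 1 estimate of the spread, the p-values of each comparison rest on both pairs. The spreads of both pairs thus enter every p-value. Over all tested genes the H1.5 pair was not the tighter one, as its arrays correlated at 0.801 and the SIRT1 arrays at 0.897. With each knockdown fitted alone, 2001 genes were called in the H1.5 knockdown and 3601 in the SIRT1 knockdown. The number of arrays, 2 per knockdown, limits the precision of every value.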

Results

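Gene expression was measured in IMR90 fetal lung fibroblasts after knockdown of H1.5, a linker histone that binds DNA between nucleosomes, and after knockdown of SIRT1, an NAD-dependent deacetylase of histones and other proteins. Each of the 4 arrays compared knockdown cells (Cy5) with control knockdown cells (Cy3), and each knockdown had 2 arrays. Log2 ratios of knockdown over control are given below as mean ± SD of the 2 arrays (n = 2). Across genes, which are not independent replicates, the log2 ratios of the 2 H1.5 arrays correlated at 0.801, those of the 2 SIRT1 arrays at 0.897, and arrays of different knockdowns at 0.464 to 0.525.

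Most signals were close to background. The median Cy3 signal of an array was 40.4 to 42.6 intensity units over a median background of 36 to 39, and the median Cy5 signal was 50.3 to 50.8 over 42 to 43.5. Between 48.6% and 51.3% of spots were well above background in Cy3 and 39.4% to 45% in Cy5. Brightness followed the base composition of the probe. Probes of at most 30% GC had a median Cy3 signal of 34.5, and those above 65% GC had 14170, with 40.8% of their spots saturated. Between 483 and 771 spots per array were saturated in Cy3 and 555 to 825 in Cy5.

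The knocked-down genes themselves were measured by dim probes. HIST1H1B (now H1-5), read by a probe on chromosome 6 at 27942608 to 27942667 (hg17), was not well above background in either channel of the H1.5 arrays. Its log2 ratio was -0.01 ± 0.03 in the H1.5 knockdown (adjusted p = 0.785) and 0.01 ± 0.04 in the SIRT1 knockdown (adjusted p = 0.977). On both SIRT1 arrays this probe was well above background in Cy3 but not in Cy5. The scanner's own ratio, which replaces values near background, was -1.43 ± 0.21 on the H1.5 arrays and 0.40 ± 0.20 on the SIRT1 arrays. With the series matrix score, which is proportional to that ratio, the H1.5 gene was called lower in the H1.5 knockdown (-2.49). The SIRT1 probe, on chromosome 10 at 69347566 to 69347625, was not well above background in any of 8 channels and did not enter the test, with a ratio of 0.01 ± 0.01 in the SIRT1 knockdown. The depth of either knockdown was therefore not measurable on these arrays.

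The first comparison asked which transcripts changed when H1.5 was depleted. The largest falls were small. PKM, the glycolytic pyruvate kinase, stood at -0.57 ± 0.02 (0.674 of control, adjusted p = 0.000687), and FTL, the light chain of the iron store ferritin, at -0.56 ± 0.03. The translation elongation factors EEF2 and EEF1A1 stood at -0.48 ± 0.03 and -0.44 ± 0.01. TPM2, a tropomyosin of actin filaments, was at -0.53 ± 0.02, and ZYX, which encodes the focal adhesion protein zyxin, at -0.49 ± 0.04. Also lower were TTYH2 (-0.52 ± 0.04, the sign shared by 1 of its 2 probes), a membrane protein of the tweety family, ORC1 (-0.49 ± 0.06), a subunit of the origin recognition complex, LGALS1 (-0.48 ± 0.01), which encodes galectin-1, and GNAI2 (-0.46 ± 0.07), a G protein subunit. FTHL17, a ferritin heavy chain relative, stood at -0.44 ± 0.06. All of these genes except FTL and FTHL17 were also called lower in the SIRT1 knockdown. TPM2, TTYH2 and LGALS1 fell further there, to -0.91, -0.88 and -0.83. PKM (-0.49 there), ZYX (-0.54), EEF1A1 (-0.46) and GNAI2 (-0.28) had no called difference between the knockdowns. Falls common to both knockdowns could not be told apart from effects of a shared control or the dyes.

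The largest rises were mostly of probes whose control channel was not well above background. GPBP1, a promoter-binding protein, was at least 2.08-fold higher (adjusted p = 0.000621), FCHO1, an endocytic protein, at least 2.06-fold, and ZNF224 and ZNF318, zinc finger proteins, at least 2.10-fold and 2.04-fold. EID3 was at least 2.08-fold higher, SLC2A4, the insulin-regulated glucose transporter, at least 1.99-fold, and MRAS, a Ras-related GTPase, at least 1.87-fold. PHTF2, CDC42EP4, SSH2 and HDAC5 were well above background in both channels of both arrays, and HLTF was not so on every array in the control channel. PHTF2 stood at 0.99 ± 0.01, CDC42EP4, an effector of the GTPase CDC42, at 0.98 ± 0.06, and SSH2, a phosphatase of cofilin, at 0.97 ± 0.05. HDAC5, a histone deacetylase, was at 0.97 ± 0.01 (the sign shared by 2 of its 3 probes) and HLTF, a helicase-like chromatin factor, at 0.97 ± 0.11 (1 of 2 probes). The probes of CDC42EP4, SSH2 and HDAC5 were bright, with mean log2 signals of 15.31, 15.07 and 14.3. Of all 336 genes at 13 to 15, 263 were called higher in this knockdown and 15 lower, with a median of 0.35. Above 15, 234 of 788 were higher and 4 lower, with a median of -0.06. Rises were therefore common among bright probes, and whether these are particular to their genes was not tested. All of the named rises except CDC42EP4 and SSH2 were also called higher in the SIRT1 knockdown. For each of these but MRAS the difference between the knockdowns was called as well, higher in the H1.5 knockdown. The part common to both knockdowns could not be told apart from effects of a shared control or the dyes.

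Of the 16597 genes tested with limma, 4286 were called in the H1.5 knockdown, 2478 higher and 1808 lower. The changes were small on this scale, which the offset compresses for dim probes. The median was 0.19 among the genes called higher and -0.16 among those called lower. On the log2 scale 15 genes changed by at least 1, all upward. The count was 19 with the scanner's processed signals (all higher) and 526 with the series matrix, 6773 without H1.5 replicate 1 and 2001 without SIRT1 replicate 1 or, likewise, without SIRT1 replicate 2. Probes with Cy5 well above background on all 4 arrays and Cy3 on none belonged to 168 genes, and 146 of these were called higher in both knockdowns and 0 lower in both. In the mirror set, Cy3 well above background on all 4 arrays and Cy5 on none, 0 of 302 genes were called lower in both (limma). With no dyes exchanged, a dye effect and a change common to both knockdowns were confounded in the first set. Selecting probes by a bright Cy5 and a dim Cy3 channel also favours a high ratio, so the direction of its calls is partly built in.

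Of the fixed lists, 6 were called in the H1.5 knockdown. Without H1.5 replicate 1 the calls of the mitochondrial respiratory chain (adjusted p = 0.0549) and NRF2 targets (adjusted p = 0.0828) were lost. With processed signals, and also with the series matrix, the call of hypoxia response genes was lost. Cytosolic ribosomal protein genes, which encode the protein part of the ribosome, were lower: 34 of 77 fell, 10 rose and 33 did not pass (38 and 10 adjusted over the list alone), with a median of -0.09 (camera, adjusted p = 0.000151, and adjusted p = 0.636 with an estimated correlation). The list was brighter than all tested genes, with a median log2 signal of 8.69 against 7.19. Of all 1200 genes at 8 to 9, 388 were called lower and 227 higher (median -0.03). At 9 to 11, 207 of 523 were lower and 103 higher (median -0.06). Lower calls were thus common among genes this bright, and no random lists matched on brightness were drawn for this list. RPL29 stood at -0.42 ± 0.00 and RPL26 at -0.33 ± 0.01. RPS13, read by a probe saturated on the SIRT1 arrays, was at 0.47 ± 0.02, but at -0.02 with the scanner's processed signals and at -0.06 with an unsaturated probe. Core histone genes, which encode the nucleosome proteins, fell in 17 of 58 cases and rose in 0 (18 and 0 adjusted over the list alone), with a median of -0.07 (adjusted p = 0.00169, and adjusted p = 0.884 with an estimated correlation). H2AC21 was at -0.30 ± 0.05, H2BC7 at -0.24 ± 0.06, H3C6 at -0.23 ± 0.05 and H2AC14 at -0.19 ± 0.01.

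Targets of NRF2, the regulator of the antioxidant response, fell in 4 of 17 cases and rose in 0 (4 and 0 adjusted over the list alone), with a median of -0.06 (adjusted p = 0.00622, and adjusted p = 0.636 with an estimated correlation). Beside FTL these were TXN (-0.39 ± 0.01), PRDX1 (-0.32 ± 0.03) and TXNRD1 (-0.16 ± 0.03), which encode thioredoxin, a peroxiredoxin and thioredoxin reductase. Hypoxia response genes fell in 6 of 24 cases and rose in 1 (7 and 1 adjusted over the list alone), with a median of -0.06 (adjusted p = 0.00947, and adjusted p = 0.636 with an estimated correlation). They included the glycolytic enzymes ENO1 (-0.41 ± 0.00) and LDHA (-0.24 ± 0.06), the collagen crosslinker LOX (-0.23 ± 0.00) and NDRG1 (-0.18 ± 0.01). Nuclear genes of the mitochondrial respiratory chain fell in 11 of 78 cases and rose in 3 (10 and 1 adjusted over the list alone), with a median of -0.03 (adjusted p = 0.0106, and adjusted p = 0.636 with an estimated correlation). Examples were UQCR11 (-0.26 ± 0.06), NDUFS8 (-0.26 ± 0.10), NDUFB9 (-0.21 ± 0.03, the sign shared by 1 of 2 probes) and DMAC2L (-0.19 ± 0.05). Olfactory receptor genes rose in 13 of 65 cases and fell in 2 (12 and 2 adjusted over the list alone), with a median of 0.07 (adjusted p = 0.00622, and adjusted p = 0.636 with an estimated correlation). OR10A5 was at 0.61 ± 0.03, OR5H1 at 0.49 ± 0.01, OR1L3 at 0.30 ± 0.00, and OR11A1 at 0.54 ± 0.01, the last turning to -0.17 with processed signals. The probes of OR10A5, OR5H1 and OR11A1 were bright, with mean log2 signals of 13.65, 13.26 and 15.83, against a list median of 7.17. Of all 336 genes at 13 to 15, 263 were called higher in this knockdown and 15 lower.

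**Figure D1:**
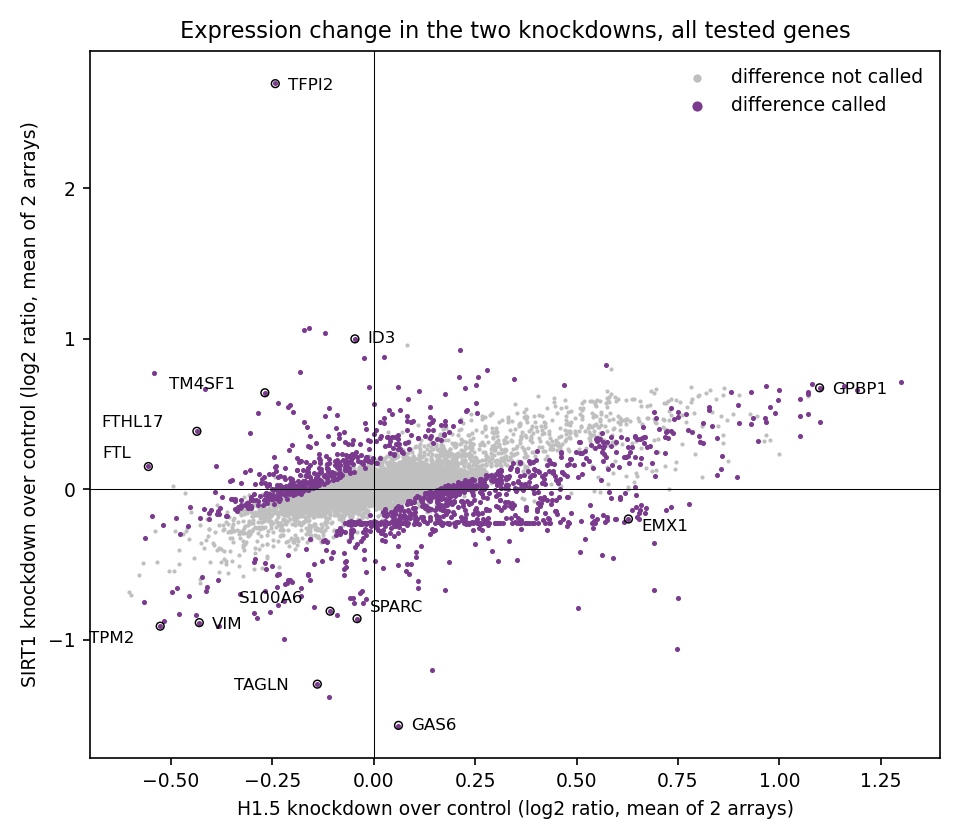
Each point is 1 of the 16597 tested genes, at its log2 ratio in the H1.5 knockdown (x axis) and in the SIRT1 knockdown (y axis), means of 2 arrays each; purple points have a called difference between the knockdowns and circles mark named genes. The row of purple points at about -0.22 on the y axis holds probes whose signals were saturated.

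The second comparison asked which transcripts changed when SIRT1 was depleted. GAS6, a secreted ligand of the TAM receptor kinases (chromosome 13, 113582334 to 113582393), fell to 0.337 of control (-1.57 ± 0.09, adjusted p = 0.000343), and TAGLN, the smooth muscle actin-binding protein transgelin (chromosome 11, 116579784 to 116580173), to 0.408 of control (-1.29 ± 0.01, adjusted p = 0.00019). TFPI2, a secreted inhibitor of serine proteases (chromosome 7, 93161226 to 93161285), rose 6.48-fold (2.70 ± 0.13, adjusted p = 0.00019). ID3, an inhibitor of basic helix-loop-helix transcription factors (chromosome 1, 23630972 to 23631031), rose 2.00-fold (1.00 ± 0.06, adjusted p = 0.000389).

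The other falls named by the rule were smaller. TPM2 stood at -0.91 ± 0.09, VIM, the intermediate filament vimentin, at -0.89 ± 0.08, TUBA1C, a tubulin, at -0.85 ± 0.02, and MYL9, a myosin light chain, at -0.78 ± 0.05. SPARC, a matrix glycoprotein, was at -0.86 ± 0.11, LGALS1 at -0.83 ± 0.05, and the calcium-binding proteins ANXA2 and S100A6 at -0.82 ± 0.03 and -0.81 ± 0.02. RTN4, a protein of the endoplasmic reticulum, was at -0.91 ± 0.03 and TTYH2 at -0.88 ± 0.06 (1 of 2 probes). Among the other rises, JUND, a component of the AP-1 transcription factor, stood at 0.80 ± 0.04, ILDR1 at 0.79 ± 0.08, ANKK1 at 0.74 ± 0.01, SDK1, a cell adhesion protein, at 0.69 ± 0.07, and SLC27A1, a fatty acid transporter, at 0.67 ± 0.04. HDAC5 was at 0.68 ± 0.09 and AGPAT3, an acyltransferase, at 0.68 ± 0.05, each by its brightest probe, whose sign the other 2 of its 3 probes did not share. GPBP1 was at least 1.60-fold higher and RALGAPA1 at least 1.59-fold, their control channel not being well above background.

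**Figure D2:**
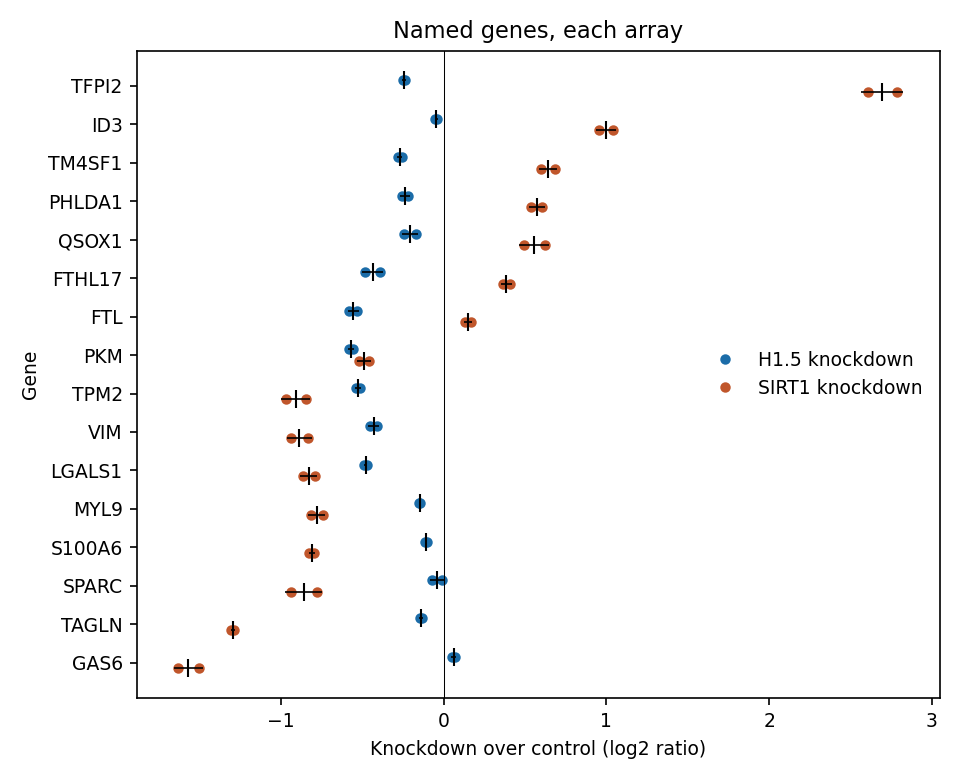
Log2 ratio of knockdown over control (x axis) for 16 named genes (y axis); dots are single arrays of the H1.5 (blue) and SIRT1 (orange) knockdowns, ticks are means and bars 1 SD of the 2 arrays. TFPI2 lies at 2.70 in the SIRT1 knockdown and -0.24 in the H1.5 knockdown, and GAS6 at -1.57 and 0.06.

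In the SIRT1 knockdown 2591 of 16597 genes were called, 1144 higher and 1447 lower, and 9 changed by at least 1 on the log2 scale, 4 of them upward. The median change was 0.27 among genes called higher and -0.22 among those called lower. Of the 1447 genes called lower, 668 were read by a probe saturated on some array, whose ratios lay close to a common value of -0.22; with saturated probes left out, an alternative chosen after the data were seen, 1130 genes were called higher and 737 lower. The count fell to 431 without SIRT1 replicate 1 and to 467 without SIRT1 replicate 2, rose to 4477 with no background subtraction, and with median centring in place of loess was 5598, of which 5545 were higher.

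Of the fixed lists, 6 were called in the SIRT1 knockdown. With median centring 2 of these calls were lost and the direction of the test turned for 1, the ribosomal proteins. With the series matrix 1 call was lost. Contractile myofibroblast genes fell in 11 of 22 cases and rose in 2 (11 and 2 adjusted over the list alone), with a median of -0.11 that turned to 0.03 with median centring (adjusted p = 3.72e-05, and adjusted p = 0.458 with an estimated correlation). TAGLN, TPM2 and MYL9 were among the members with the smallest p. Fibrillar collagen and matrix genes fell in 13 of 33 cases and rose in 3 (14 and 3 adjusted over the list alone), with a median of -0.05 that turned to 0.04 with median centring (adjusted p = 0.00117, and adjusted p = 0.458 with an estimated correlation). The matrix proteins THBS1 and FN1 stood at -0.68 ± 0.03 and -0.66 ± 0.03, and LOX at -0.56 ± 0.07. Hypoxia response genes fell in 8 of 24 cases and rose in 0 (9 and 1 adjusted over the list alone), with a median of -0.06 (adjusted p = 3.72e-05, and adjusted p = 0.458 with an estimated correlation). ENO1 and LDHA were both at -0.65, with SDs of 0.04 and 0.03.

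Core histone genes rose in 22 of 58 cases and fell in 2 (29 and 2 adjusted over the list alone), with a median of 0.08 (adjusted p = 2.83e-10, and adjusted p = 0.466 with an estimated correlation). H4C8 was at 0.45 ± 0.05, H4C14 at 0.40 ± 0.00, H2BC17 at 0.23 ± 0.03, and H4C11 at -0.34 ± 0.06 (0.84 with median centring). Targets of NF-kB, the transcription factor of inflammatory signalling, rose in 7 of 23 cases and fell in 1 (7 and 1 adjusted over the list alone), with a median of 0.05 (adjusted p = 0.000625, and adjusted p = 0.458 with an estimated correlation). NFKB1, a subunit of the factor, was at 0.54 ± 0.02, SOD2, mitochondrial superoxide dismutase, at 0.54 ± 0.00, the chemokine CCL2 at 0.29 ± 0.05, and PTX3, a secreted pattern recognition protein, at -0.45 ± 0.07. Ribosomal protein genes fell in 27 of 77 cases and rose in 8 (34 and 14 adjusted over the list alone), with a median of -0.07 that turned to 0.36 with median centring (adjusted p = 0.00784, and adjusted p = 0.458 with an estimated correlation). Of all 1200 genes at a mean log2 signal of 8 to 9, 258 were called lower in this knockdown and 189 higher. At 9 to 11, 182 of 523 were lower and 132 higher. RPL29 was at -0.39 ± 0.02, RPL31 at -0.28 ± 0.04, RPS21 at -0.26 ± 0.00 and RPS3 at 0.39 ± 0.02. With median centring RPL29 turned to 0.045, RPL31 to 0.049 and RPS21 to 0.18.

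Other fixed lists were not called by camera in either knockdown, but fry called some of them. In the SIRT1 knockdown fry called linker histones higher (adjusted p = 0.0172) and epithelial (0.0334) and haematopoietic markers (0.0234) lower. In the H1.5 knockdown it called neuronal markers and the senescence and secretory list higher (0.0130 each). It called the S phase list higher in both (0.0397 in H1.5, 0.0234 in SIRT1). The adjusted p-values that follow are camera's. The linker histone list (8 genes measured) had adjusted p = 0.793 in the H1.5 knockdown and 0.102 in the SIRT1 knockdown, and the list of H3K9 methylation and heterochromatin factors had 0.958 and 0.676. The S phase list had 0.958 and 0.413, the G2/M list 0.878 and 0.676, the p53 targets 0.878 and 0.184, and the senescence and secretory list 0.778 and 0.349. Markers of cell types that a fibroblast culture should lack were tested too. Epithelial markers had adjusted p = 0.878 in the H1.5 knockdown and 0.102 in the SIRT1 knockdown, endothelial markers 0.878 and 0.676, haematopoietic markers 0.958 and 0.175, and neuronal markers 0.774 and 0.517, and markers of fibroblast identity 0.878 and 0.854. In the H1.5 knockdown the p53 targets had a median of -0.02 and a mean of 0.02, and the epithelial markers a median of -0.01 and a mean of 0.01, with the test pointing down for both lists. The fibroblast list in the SIRT1 knockdown had a median of 0.01 and a mean of -0.03, with the test pointing up.

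The third comparison set the knockdowns against each other, a contrast in which a dye effect of the same size on all arrays cancels. GAS6 and TAGLN were higher in the H1.5 knockdown than in the SIRT1 knockdown, by 1.63 ± 0.05 and 1.16 ± 0.03 (difference ± SE, adjusted p = 0.000985 and 0.000671). TFPI2 was lower by -2.94 ± 0.07 (adjusted p = 0.000601), ID3 by -1.05 ± 0.04, TM4SF1, a membrane protein of the tetraspanin kind, by -0.91 ± 0.04, FTHL17 by -0.82 ± 0.04, PHLDA1 by -0.81 ± 0.04 and QSOX1, a sulfhydryl oxidase, by -0.76 ± 0.06. Of the 25 genes named for this comparison, 24 were no longer called with the scanner's processed signals (adjusted p = 0.0661 for both GAS6 and TAGLN) and 25 with the series matrix (adjusted p = 0.105 for both). EPHX3, TCL1A, PIAS4 and EMX1 were also taken by the rule as higher in the H1.5 knockdown, but their probes were saturated on both SIRT1 arrays in at least 1 channel, so no size of the difference is given, and its sign turned with median centring.

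Core histone genes were lower in the H1.5 knockdown than in the SIRT1 knockdown in 25 of 58 cases and higher in 2 (38 and 2 adjusted over the list alone), with a median difference of -0.20 (adjusted p = 4.45e-17, and adjusted p = 0.582 with an estimated correlation). H4C14 differed by -0.39 ± 0.03 and H3C3 by -0.36 ± 0.03. NRF2 targets were lower in 4 of 17 cases and higher in 1 (4 and 1 adjusted over the list alone), with a median of -0.10 (adjusted p = 0.00166, and adjusted p = 0.582 with an estimated correlation), FTL by -0.71 ± 0.04 and TXN by -0.37 ± 0.03. Ribosomal protein genes were lower in 11 of 77 cases and higher in 7 (15 and 8 adjusted over the list alone), with a median of -0.06 that turned to 0.05 with no background subtraction (adjusted p = 0.00216, and adjusted p = 0.582 with an estimated correlation). Of all 1200 genes at a mean log2 signal of 8 to 9, 120 had a difference called lower and 85 higher. At 9 to 11, 84 of 523 were lower and 76 higher. RPLP0 differed by -0.35 ± 0.03, and no size is given for RPS13, whose probe was saturated on the SIRT1 arrays.

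**Figure D3:**
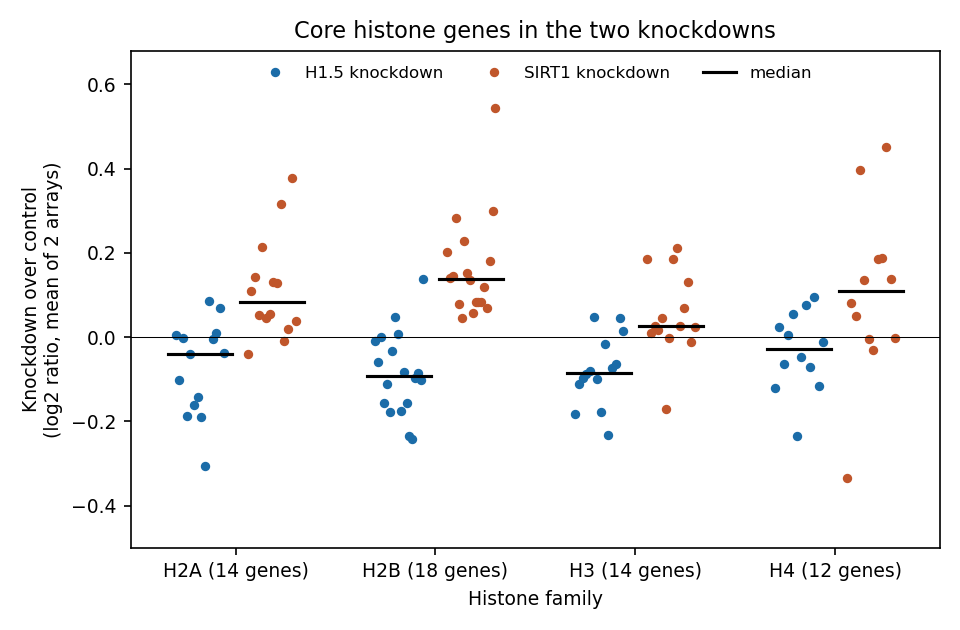
Log2 ratio of knockdown over control (y axis) for the 58 core histone entries by family (x axis). Each dot is 1 entry's mean of 2 arrays in the H1.5 (blue) or SIRT1 (orange) knockdown, and lines are medians. A few genes entered under both an old and a current symbol. Family medians lie between -0.09 and -0.03 in the H1.5 knockdown and between 0.03 and 0.14 in the SIRT1 knockdown.

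Contractile genes were higher in the H1.5 knockdown than in the SIRT1 knockdown in 7 of 22 cases and lower in 2 (9 and 2 adjusted over the list alone), with a median of 0.10 that turned to -0.13 with median centring (adjusted p = 0.00444, and adjusted p = 0.582 with an estimated correlation). ACTG2, a smooth muscle actin, differed by 0.77 ± 0.05. Wnt targets were higher in 7 of 15 cases and lower in 0 (8 and 0 adjusted over the list alone), with a median of 0.16 that turned to -0.07 with median centring (adjusted p = 0.00444, and adjusted p = 0.582 with an estimated correlation). They included DKK3 (0.53 ± 0.03), a secreted protein of a family of Wnt antagonists, and CCND1 (0.49 ± 0.05), the cell cycle regulator cyclin D1, which turned to -0.091 with median centring. Late envelope and small proline-rich protein genes, which belong to the skin barrier, were higher in 8 of 19 cases and lower in 0 (9 and 0 adjusted over the list alone), with a median of 0.11 that turned to -0.32 with median centring (adjusted p = 0.00216, and adjusted p = 0.582 with an estimated correlation). Of these probes 36.8% were saturated on some array, against 4.71% of all tested genes. Among all 781 genes with a saturated probe, 740 were called higher in this contrast and 0 lower, so calls of saturated members carry little information. SPRR1A was read by a probe saturated on the SIRT1 arrays, so no size is given. LCE2D differed by 0.49 ± 0.07, which turned to -0.88 with median centring. Olfactory receptor genes were higher in 6 of 65 cases and lower in 0 (6 and 0 adjusted over the list alone), with a median of 0.05 that turned to -0.03 with median centring (adjusted p = 0.0347, and adjusted p = 0.582 with an estimated correlation), OR1L3 by 0.27 ± 0.03 and OR11A1 by an amount not given, its probe being saturated on the SIRT1 arrays.

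The difference was called for 1798 of 16597 genes, 1360 higher in the H1.5 knockdown and 438 lower, and 17 differed by at least 1 on the log2 scale. Of the 1360, 740 were read by a probe saturated on some array; with such probes left out the counts were 487 higher and 320 lower. The total was 1 with the scanner's processed signals, 0 with the series matrix (limma; 3115 at an unadjusted p under 0.05), 292 without SIRT1 replicate 1, 107 without SIRT1 replicate 2, 3887 without H1.5 replicate 1 and 3636 without H1.5 replicate 2, and with median centring 4887 of 4940 genes were lower in the H1.5 knockdown.

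**Figure D4:**
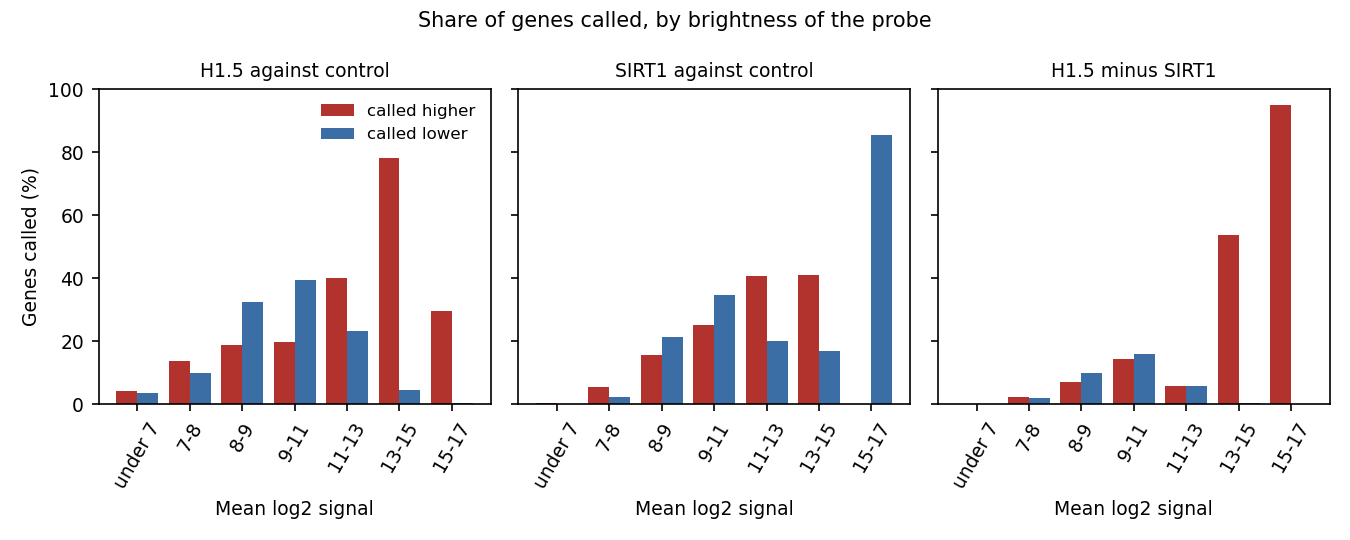
Share of genes called higher (red) and lower (blue), in percent (y axis), by the mean log2 signal of the probe (x axis), for the H1.5 knockdown, the SIRT1 knockdown and their difference. Of the 788 genes with a mean log2 signal above 15, 749 were called higher in the H1.5 than in the SIRT1 knockdown and 672 were called lower in the SIRT1 knockdown.

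The knockdowns shared many calls. In both, 782 genes were called higher and 493 lower, where independent calls would give 171 and 158, and 225 were called in opposite directions, where independent calls would give 341. All 225 also had a called difference between the knockdowns. Across genes the 2 sets of log2 ratios correlated at 0.534, with a covariance of 0.0109. Unchanged knockdowns simulated against 1 common control gave a median of 166 shared calls in 20 draws, at most 250, a correlation of 0.666 and a covariance of 0.00241. The control channels, which correlated at 0.996 to 0.999 across probes, could not be split, so a change shared by the knockdowns, a shared control and the dye orientation common to all arrays were not separable.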

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

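Of the tests in this part, those on GC content and brightness were planned before their result was seen, and the tests on histone families, the S phase list, stretches of the mitochondrial chromosome, the nuclear respiratory chain, saturation and the bright end of the loess curve were chosen after it. The values of mitochondrial probes under other scalings were also added after it. The contrast between knockdowns itself was planned.

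Of the fixed lists, 7 differed between the knockdowns by the test of the difference (limma's camera with a preset correlation). Medians of the H1.5 knockdown minus the SIRT1 knockdown were -0.20 for core histones, -0.10 for NRF2 targets, -0.056 for cytosolic ribosomal proteins, 0.16 for Wnt targets, 0.11 for late envelope and small proline-rich proteins, 0.10 for contractile myofibroblast genes and 0.047 for olfactory receptors. With an estimated correlation 0 of the 47 lists passed (adjusted p = 0.582 for each of these), 2 had an unadjusted p under 0.05, and fry called 16. Of the 7 calls, 4 were lost with processed signals. Leaving out saturated probes lost 1 call and left 3 lists higher and 3 lower. With no background subtraction, and also with the series matrix, 3 were lost and camera's direction turned for 1, and median centring did the same. Camera's direction compares a list with all other genes and is not the sign of its median. With median centring the medians of 4 of the 7 lists turned sign: -0.32 for late envelope genes, -0.13 for contractile genes, -0.072 for Wnt targets and -0.029 for olfactory receptors. Core histones were called in the same direction under all of these scalings. In addition, 225 genes were called in opposite directions in the knockdowns, each with a called difference. Of these, 54 were lower in the H1.5 knockdown and higher in the SIRT1 knockdown. The other 171 went the other way, 117 of them read by a saturated probe. Spike-in spots, which no comparison used, were well above background in 67.5% of cases in Cy3 and 58.8% in Cy5, against 0.163% of negative control spots in either channel.

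Core histone transcripts were lower in the H1.5 knockdown than in the SIRT1 knockdown, with the same direction and a camera call under processed signals (-0.61), no background subtraction (-0.33), median centring (-0.46) and the series matrix score (-0.94). The call was lost with an estimated correlation (adjusted p = 0.582). The GC content and brightness of the probes as the whole cause were argued against, since the median lay at percentile 0 of 10000 random lists matched on both, whose medians ran from -0.06 to 0.06. A single histone transcript read by many probes was argued against by the families, whose medians were -0.21 for H2A, -0.23 for H2B, -0.12 for H3 and -0.11 for H4. Histone genes share sequence within a family, so single genes are less certain than families. A smaller share of cells in S phase stayed open: the S phase list had a median of -0.011, and 87.0% of its 23 genes lay above -0.1, short of the share set as the bound, with 16 of the genes well above background in both channels on all arrays. RNA quality and the amplification of these transcripts were not tested. A difference between the knockdowns in histone transcript levels therefore stays only one of the candidate explanations.

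Transcripts of the mitochondrial chromosome were higher in the H1.5 knockdown than in the SIRT1 knockdown. Of 13 unsaturated probes, 10 were called higher and 0 lower (limma), with a median difference of 0.55. With no background subtraction 8 were called higher and 0 lower (median 0.77). With processed signals and with the series matrix 0 were called (limma), 8 being higher at an unadjusted p under 0.05 in each and 0 lower, with medians of 0.68 and, on the score's scale, 1.04. With median centring the median was -0.12, 5 probes being called higher and 5 lower, so the direction depends on that choice. The explanations below were tested with loess only. The probe named ENST00000361390 differed by 1.29 ± 0.04 (SE, adjusted p = 0.000669), ENST00000361681 by 1.00 ± 0.05 and AK097322 by 0.93 ± 0.04. GC content and brightness were argued against, with the median at percentile 100 of matched lists, whose medians ran from -0.18 to 0.42. A single short transcript was argued against by the 7 separate stretches, over 500 bases apart, that held a probe called higher. Probe positions cannot tell 1 long transcript that spans these stretches from several transcripts. For a joint change with the nuclear genes of the respiratory chain, these had a median of -0.010. All 78 (100%) lay below the median of the mitochondrial probes. That bound decides little, because the differences of all genes had an SD of 0.14 and most lists would meet it. The nuclear list showed no rise as a whole. Its probes were dim (median log2 signal 7.35, against 8.265 or more for the unsaturated mitochondrial probes), so a smaller joint change stays open. RNA quality and the amplification of these transcripts were not tested, and the direction was lost under median centring, so a change in mitochondrial transcript levels may be offered only as a hypothesis.

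The brightest probes were called higher in the H1.5 knockdown than in the SIRT1 knockdown. Of the 740 called genes with a saturated probe, 80.8% (598) had both channels saturated on both SIRT1 arrays. Their SIRT1 ratios set clipped signals against each other and gave no measure of expression. Across all 781 saturated genes that ratio had a median of -0.22. The called differences of the 598 therefore cannot be read as differences in expression. For the rest of the 740, saturation is a candidate explanation. Among 343 bright unsaturated genes (mean log2 signal above 13) 190 were called higher and 2 lower, with a median of 0.24. Under median centring that median was -0.996, so the direction of these calls may come from the loess curve at the bright end. No biological explanation was tested for this pattern.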

How the results depend on the processing

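The offset, GC and saturation alternatives, and the averaged H1.5 arrays, were chosen after the data were seen. The counts of called genes were 4286 (H1.5 knockdown), 2591 (SIRT1 knockdown) and 1798 (difference), and the numbers below follow that order where 3 are given. Unless said otherwise, the cause was not tested.

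A size minimum of 1 left 15, 9 and 17 genes, and 0 shared. Processed signals gave 19 genes in the H1.5 knockdown, 1 for the difference, 19 shared, a correlation of 0.73, 10 lists in the SIRT1 knockdown, 0.54 for the SIRT1 gene, and reversed OR11A1 (-0.17) and RPS13 (-0.018) in the H1.5 knockdown. They moved the median of all genes to -0.12 and -0.16 in the H1.5 and SIRT1 knockdowns. No background subtraction gave 2344, 4477 and 1030 genes, a correlation of 0.67 and -0.053 for the SIRT1 gene, and reversed the ribosomal proteins in the difference (0.048).

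Median centring gave 1096, 5598 and 4940 genes, 551 shared, a correlation of 0.41, 3 lists for the difference and -0.028 for the SIRT1 gene. In the SIRT1 knockdown it reversed the ribosomal proteins (0.36), H4C11 (0.84), RPL29 (0.045), RPL31 (0.049) and RPS21 (0.18). In the difference it reversed the late envelope list (-0.32), EPHX3 (-0.50), TCL1A (-0.53), PIAS4 (-0.55), EMX1 (-0.56), OR11A1 (-0.63), SPRR1A (-0.80), LCE2D (-0.88), RPS13 (-0.72) and CCND1 (-0.091). EPHX3, TCL1A, PIAS4, EMX1, OR11A1, SPRR1A and RPS13 were read by probes saturated on the SIRT1 arrays, so these values give no size. The series matrix gave 526, 1575 and 0 genes (limma; 3115 for the difference at an unadjusted p under 0.05), 320 shared and a correlation of 0.74. It gave OR11A1 at -0.14 in the H1.5 knockdown, the late envelope list of the difference a median of 0.034 with the test pointing down, and the H1.5 gene a score of -2.49 (adjusted p = 0.036, against 0.0566 to 0.920 over the other alternatives). It moved the median of all genes to -0.11 in the SIRT1 knockdown.

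With no filter 676 genes had a called difference, and with a strict filter the correlation was 0.46. Fitted alone, the H1.5 knockdown had 2001 genes. Taking the replicate number as a block gave 5581, 3301 and 2844 genes, although deviations of arrays with the same number correlated at only -0.02 across genes, so the numbers gave no pairing. An offset of 1 gave 1375 genes in the SIRT1 knockdown and 125 for the difference, probes above 55% GC left out 955 for the difference, and saturated probes left out 807, a correlation of 0.60 and RPS13 at -0.061 in the H1.5 knockdown. With an estimated correlation camera called 0 lists in each comparison (2, 5 and 2 at an unadjusted p under 0.05), while fry called 20, 20 and 16.

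With each array left out in turn, the lone array being assumed to vary like the other knockdown's pair, the counts ran from 2001 to 6773, from 431 to 3601 and from 107 to 3887, with 298 to 1771 shared, a correlation of 0.49 to 0.55 and an H1.5 gene of -0.033 to 0.010. The lowest SIRT1 count was without SIRT1 replicate 1, the lowest difference count without SIRT1 replicate 2, and both highest counts of the H1.5 knockdown and the difference without H1.5 replicate 1, which also reversed the uncalled H1.5 gene.

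Aquantile, the mean over probes, the trended prior, the GC loess and the averaged H1.5 arrays left the 3 counts within 1.5 times. Of the named genes, 3 of 47 in the H1.5 knockdown, 17 of 42 in the SIRT1 knockdown and 0 of 25 in the difference kept direction and call under the alternatives that gave them a value, the size minimum of 1 not counted. The 3 were FCHO1, HLTF and ZNF318, and the 17 included TFPI2, ID3, GAS6, TAGLN, SPARC and TPM2. The control channel of FCHO1 and ZNF318 was not well above background on either H1.5 array, and that of HLTF not on every one. FCHO1, ZNF318 and HLTF were also called higher in the SIRT1 knockdown, by at least 1.55-fold, 1.51-fold and 1.36-fold. A dye effect and a shared change were therefore confounded for them. FCHO1 and ZNF318, with 1 probe each, had no value under the strict filter. Signal over background limits all of this: with 48.6% to 51.3% of spots well above background in Cy3 and 39.4% to 45% in Cy5, both targets were too dim to measure and folds of dim probes are bounds.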

Other observations

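The genes in this part were chosen after their values were seen, and no test was added for them. Among the 54 genes called lower in the H1.5 knockdown and higher in the SIRT1 knockdown were IGFBP5, a binding protein of insulin-like growth factors (-0.21 ± 0.02 and 0.54 ± 0.07), EPAS1, a hypoxia-inducible transcription factor (-0.30 ± 0.04 and 0.37 ± 0.00), and GREM1, an antagonist of bone morphogenetic proteins (-0.24 ± 0.00 and 0.15 ± 0.02), each as mean ± SD of 2 arrays. FTL stood at -0.56 ± 0.03 and 0.15 ± 0.02, and FTHL17 at -0.44 ± 0.06 and 0.39 ± 0.03. Ferritin genes and pseudogenes share sequence, so these probes need not read 1 gene.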
